A study of Mus musculus with 2 samples.

How the data were processed

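Total RNA of mouse hippocampus was amplified, labelled with biotin and hybridised to Illumina whole-genome bead arrays, per the labels' protocols. The labels give 1 sample treated with CeCl3 and 1 control, both male ICR mice with an age of 4 weeks, and the grouping was taken from the labels alone. Since dosing lasted 90 days, 4 weeks cannot be the age at which the tissue was taken. The software BeadStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here.

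The deposited probe table holds, per the file headers, the mean signal intensity of each bead type, the standard error over its beads, the number of beads and a detection p-value. The detection p-value deposited for each probe is BeadStudio's comparison with negative control beads, per the file headers, and is not adjusted. The bead numbers, per the file headers, ranged from 12 to 137 on the CeCl3 array and from 15 to 157 on the control array. The deposited intensity is background-subtracted, since 27.1% of values on each array lie below 0. Although the table is called not normalized, the 1st to 99th percentiles of its 2 arrays differ by at most 0.509%, so its values appear to be normalized between arrays already. The intensity values deposited in the series matrix rank the probes of each array in the same order (Spearman correlation 1) but have unequal quantiles, with a ratio of 1.28 between the 75th percentiles, and so appear not to be normalized between arrays. Their medians were 15.9 for the CeCl3 array and 14.2 for the control array. The steps by which the authors made either table of intensity values are not given in the sources used here, so the scale of both is known from the values alone. The table with detection p-values was used as planned, and the series matrix served as an alternative.

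Signals were corrected with the normexp model of limma 3.58.1 in R 4.3.3, using negative controls inferred from the detection p-values and an offset of 16, then quantile normalized and set on the log2 scale. The offset pulls the differences of dim probes towards 0. Because the deposited values already had nearly equal quantiles, quantile normalization moved them little. A probe counted as detected at a detection p-value under 0.01, and probes detected on at least 1 array entered (18087 probes, of which 15780 were detected on both). Over the latter the arrays correlated with r = 0.984 across probes. Each gene was represented by its detected probe with the highest mean log2 signal, and for some genes other detected probes are given too. Standard errors over beads were carried to the log2 scale, and the 95% interval is 1.96 of them on either side. For signals over 500 the median coefficient of variation over beads was 34.4% on the CeCl3 array and 48.4% on the control array. For a gene detected on 1 array alone the fold is given as a lower bound, the bright signal against the lowest detected log2 signal of the other array (5.87 for CeCl3 and 6.14 for control). No fold is given where that bound is under 1. The bound leaves out bead error, so the bead interval of such a gene can reach below it. List medians and counts of members higher or lower use the measured values of such genes too; with them set at their bound, of the lists that stood apart the myelin list alone moved, to -0.14.

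Probes were named from the platform annotation, which lists 34885 probes with 1 gene symbol and 18 with several, and leaves 10378 unnamed here. Of the first, 34807 were matched by gene number to a RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols. That table was used for names alone, and no coordinates are given because the files name no genome build. Probes without a single gene symbol stayed in the counts, and 2 of them are given in the closing section by their value.

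No test across samples was possible with 1 array per group. Genes were counted at a difference of 2-fold or more. For 49 gene lists of pathways, cell types and neighbouring tissues, the median log2 difference was set among 10000 random lists of the same size, matched in 20 bins of mean signal. A list was said to stand apart under percentile 2.5 or over 97.5, as a description of these 2 arrays. The same-sign share of the 2 brightest probes of a gene was set beside 1000 random pairings of matched signal. The genes named were the 12 highest and 12 lowest among those detected on both arrays, the 5 on each side with the largest bounds among those detected on 1 array alone, the 4 members with the largest absolute difference of each list that stood apart or had a median beyond 0.2, and a fixed set of genes for learning, oxidative stress, metal binding, cell death and cell types. Further genes named in the closing section were chosen after their values were seen. The grouping, the lists, the named-gene rule, the counts and most alternatives were chosen before the data were examined. Alternatives added after seeing the data were the series matrix centred on its median, RefSeq probes alone, and cyclic loess for the counts and the same-sign share.

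Older symbols in the lists were matched through the RefSeq table. At first an alias could lead from the current symbol of one gene to another gene. This was corrected after first results had been seen; it altered the matched members of complement, glycolysis and dentate granule neurons, and no list came to stand apart or ceased to. The counting and list steps were tested on simulated data with noise of SD 0.3 for 10416 genes. They recovered 100 of 100 genes raised and 100 of 100 genes lowered by 2 on the log2 scale, with 10 other genes past 2-fold. Of 20 lists of 25 genes shifted by 0.3, 19 stood apart, against 0 of 40 unshifted lists. The measured differences of named genes were wider (SD 0.44), and the simulated genes moved independently. The simulation therefore tested the steps alone and gives no error rate for the real lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.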

Results

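Hippocampal RNA of ICR mice, an outbred stock, was measured on 2 Illumina bead arrays. The CeCl3 array held RNA of mice given cerium chloride, a salt of the lanthanide metal cerium, by gavage each day for 90 days, and the control array held RNA of mice given water. The study asked how exposure affects learning, memory and hippocampal gene expression, and the comparison of the arrays addresses the last of these. It used 300 mice in 4 groups of 75, but how many mice each array represents is not given in the sources used here. The label of the treated sample names 3 doses together (0.5, 1 and 2, in mg per kg of body weight), so the dose, or mixture of doses, on the CeCl3 array is unknown. There was 1 array per group, so no difference has a replicate check and no p-value is given. The number of arrays limits the precision, and the 95% intervals printed with single genes cover bead-to-bead error within an array alone. The arrays lay on different BeadChips, 1 group on each, so BeadChip and group cannot be told apart. Of 45281 probes, 17433 (38.5%) were detected on the CeCl3 array and 16434 (36.3%) on the control array, with a median of 42 and 44 beads per probe.

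Among genes detected on both arrays, S100a8, a calcium-binding protein abundant in neutrophils, had the largest positive difference, with a log2 difference of 2.44 (bead interval 2.12 to 2.77) between the CeCl3 and the control array. Apoa2, an apolipoprotein of high-density lipoprotein, was higher by 1.98 (1.56 to 2.40) and its second probe, detected on the CeCl3 array alone, by at least 2.44-fold. The imprinted non-coding RNA Meg3 was higher by 1.94 (1.39 to 2.48), the translation factor Eif1b by 1.90 (1.38 to 2.42), the MHC class I heavy chain H2-K1 by 1.84 (1.24 to 2.44) and the steroid dehydrogenase Hsd3b2 by 1.84 (1.42 to 2.26). Lcn2, a siderophore-binding lipocalin, was higher by 1.58 (0.99 to 2.17) and the neural adhesion molecule Chl1 by 1.53 (1.03 to 2.04). Enah, an actin regulator, was higher by 1.63 (0.94 to 2.32) on its 1 detected probe, which was designed on a cDNA clone. The kinase Oxsr1 was higher by 1.71 on its brightest probe, while another was detected on the control array alone and was at least 2.03-fold lower. Sntb2 (1.73) and Vwa5b2 (1.69) were also higher on probes designed on cDNA clones, while RefSeq probes gave -0.50 and 0.82 for Sntb2 and, detected on the control array alone, at least 1.21-fold lower for Vwa5b2. The bead intervals of this Vwa5b2 probe (-1.36 to 0.11) and of the Sntb2 probe at -0.50 (-1.14 to 0.14) held 0.

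On the lower side, the small nucleolar RNA host gene Snhg12 had a log2 difference of -4.04 (-4.48 to -3.60) on its 1 detected probe. Fcrls, an Fc receptor-like protein of microglia, lay at -2.31 (-2.62 to -2.01) and -0.46 on the 2 probes detected on both arrays, and a probe detected on the control array alone was at least 1.99-fold lower. The major urinary protein genes Mup2 and Mup3 lay at -1.80 (-2.12 to -1.48) and -1.71 (-2.23 to -1.18); they are close paralogs, so their probes may share targets. Hmgn2, a nucleosome-binding protein, lay at -1.69 (-1.95 to -1.43), the interferon-induced Ifit3 at -1.43 (-1.73 to -1.12) and the lysosomal sialidase Neu1 at -1.38 (-1.70 to -1.07). Retsat, which saturates retinol, was lower on both of its probes, at -1.37 (-1.63 to -1.11) and -1.52. The centrosomal gene Cep63 lay at -2.22 on its brightest probe and at -0.23 on the other. Zfp35 (-1.66), Myadml2 (-1.65) and Bnip5 (-1.55) completed the 12 lowest.

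Some genes were detected on 1 array alone, and for these the difference is a lower bound that leaves out bead error. Csrnp1, an early-response transcription factor, was at least 7.46-fold higher on the CeCl3 array, Scgb1a1, a secretoglobin of airway club cells, at least 4.87-fold, and Ltf, the lactoferrin of neutrophil granules, at least 3.83-fold. Nup160, of the nuclear pore, was at least 3.80-fold higher and Mxd1, of the MYC and MAX network, at least 3.13-fold. In the other direction, Xist, the RNA that silences 1 X chromosome in female cells, was at least 14.5-fold lower on the CeCl3 array. All 4 Xist probes were detected on the control array and 0 on the CeCl3 array, although both samples are labelled male. A difference in sex between the arrays therefore stays possible for every gene compared here. 4930555G01Rik was at least 3.63-fold lower, Cenpx at least 3.05-fold, Pgap3 at least 2.42-fold and Tmem168 at least 2.35-fold.

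Of 10416 named genes, 289 were at least 2-fold higher and 203 at least 2-fold lower on the CeCl3 array. Most of these were detected on 1 array alone. Among the 9473 genes detected on both arrays, 46 were 2-fold higher and 47 lower. Of the 605 and 318 genes detected on the CeCl3 or the control array alone, 16 and 14 had a bound of 2-fold or more. A bound of at least 1-fold was reached by 342 of the 605 and by all 318. The lowest detected log2 signal differed between the arrays (5.87 for CeCl3 and 6.14 for control), so 605 against 318 is no measure of direction. With the 2511 probes that have no single gene name included, the counts were 509 higher and 247 lower of 12927. These probes leaned to the CeCl3 array, with 220 higher and 44 lower. Another offset in the background correction moved the counts of 509 and 247 to 143 and 43, and limiting them to features detected on both arrays gave 103 and 53. The share of these 2-fold differences on the higher side was 67.3%, against 85.4% in the series matrix and 55.0% on RefSeq probes alone.

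Immediate early genes, which neurons switch on within minutes of activity, were lower on the CeCl3 array as a group. Of 29 measured members 22 were lower, 11 of them detected on both arrays with a bead interval below 0, and the median log2 difference was -0.26, at percentile 0.01 of random lists matched on signal. The transcription factors Fos (-1.08, bead interval -1.44 to -0.71), Egr2 (-1.26, -1.77 to -0.75) and Egr1 (-0.39, -0.65 to -0.13) and the synaptic gene Arc (-0.70, -0.94 to -0.46) were lower, and the kinase Sik1 was detected on the control array alone, at least 1.68-fold. Npas4 (-0.24, -0.77 to 0.29) and Bdnf (-0.26, -0.56 to 0.03) had intervals that held 0. Csrnp1 was the exception at the other end of the list. The median of all named genes was -0.04, so the list lay -0.23 from it.

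Genes of the modulatory transmitters were also lower on the CeCl3 array. Whether expression in hippocampal cells or the mix of tissue in the samples differed was not tested. Both arrays carried genes of the hypothalamic list, such as Pmch with a log2 signal of 11.4 (CeCl3) and 11.8 (control). Of 11 measured cholinergic genes 9 were lower, with a median of -0.28 (percentile 1.53). The choline transporter Slc5a7 lay at -0.83 (-1.18 to -0.48) and the vesicular acetylcholine transporter Slc18a3 at -0.58 (-0.91 to -0.26), while the nicotinic receptor subunits Chrna3 and Chrna5, detected on the control array alone, were each at least 1.80-fold lower. Acetylcholinesterase, Ache, lay at -0.03 (-0.36 to 0.30). Of 16 monoamine genes 12 were lower, with a median of -0.26 (percentile 0.83), among them the dopamine receptor Drd2 at -0.67 (-1.09 to -0.26) and the noradrenaline transporter Slc6a2 at -0.67 (-1.18 to -0.16). Htr4, at least 1.10-fold higher, and Drd4, with no bound above 1, were detected on the CeCl3 array alone. Over genes detected on both arrays the cholinergic list no longer stood apart, with a median of -0.19 at percentile 9.28.

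Genes of the unfolded protein response had a median of -0.21 (percentile 0.13), with 17 of 26 members lower. Chac1 lay at -0.45 (-0.70 to -0.20) and the chaperone Hsp90b1 at -0.39 (-0.70 to -0.08). The bead interval of Trib3 (-0.55, -1.26 to 0.17) held 0. Edem1 was detected on the control array alone, at least 1.55-fold lower, but its bead interval (-1.89 to 0.12) held 0 too. In the series matrix as deposited, where the median of all genes was 0.18 and not -0.04, this list lay at 0.0013 and the choroid plexus list at 0.079, so lists are read relative to all genes.

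Oligodendrocyte and myelin genes were lower in 21 of 27 members, with a median of -0.16 (percentile 0.405), or -0.14 with the members detected on 1 array alone set at their bound. The myelin protein gene Mal lay at -0.70 (-0.92 to -0.48) and at -1.23 on its second probe, the transcription factor Nkx6-2 at -0.50 (-0.71 to -0.29) and -0.95, Ugt8a, which makes the myelin lipid galactosylceramide, at -0.49 (-0.72 to -0.25). Probes of Mbp went both ways, at -0.26 (-0.43 to -0.10) on the brightest, which lies near the top of the scale, and at -0.33, 0.18 and about 0 on the others. Aspa was detected on the CeCl3 array alone, at least 1.10-fold higher, on a probe designed on a cDNA clone. Its bead interval (-0.06 to 1.14) held 0. Of the lists for tissue next to the hippocampus, the choroid plexus list stood apart. It had a median of -0.21 (percentile 1.91; 15 of 20 lower), with Cldn1 at -0.94 (-1.72 to -0.17), Col8a1 at -0.61 (-1.32 to 0.09), Lbp at -0.59 (-1.07 to -0.10) and Igfbp2 at -0.44 (-0.65 to -0.23), although Ttr, the most abundant choroid plexus transcript, lay at 0.09 (-0.18 to 0.37). The choroid plexus list stood apart under 4 of 10 alternatives, and with the mean of each gene's probes its median was -0.11 (percentile 15.6). Neocortical genes (median -0.14, percentile 3.34, 20 of 24 lower), genes of the thalamus and habenula (-0.08, percentile 23.3) and of the striatum (-0.04) lay within the random range. So did ependymal and ciliary genes (median -0.21, percentile 7.68, 8 of 11 lower) and hypothalamic and pituitary genes (median -0.21, percentile 3.49, 5 of 9 lower). The neocortical list stood apart, lower, under 2 of 10 alternatives, and the hypothalamic and pituitary list with no filter on dim probes, while with the mean of probes the latter lay at percentile 73.0. Among ependymal and hypothalamic genes, the members with the largest differences included the ciliary genes Cfap126 (-0.87) and Tekt1 (-0.65, and 0.01 on its other probe), the hormone gene Oxt (-0.88), Ecel1 (-0.68) and the neuropeptide genes Pmch (-0.43) and Avp (-0.39). Pifo (-0.48) and Pltp (0.38) had bead intervals that held 0.

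Of the 49 lists, 1 stood apart on the higher side. Genes of MHC class I and antigen processing had a median of 0.16 (percentile 98.4) with 7 of 12 members higher. H2-K1 led the list, followed by the immunoproteasome subunit Psmb8 at 0.87 (0.55 to 1.20) and H2-T23 at 0.76 (-0.05 to 1.57), whose second probe was detected on the CeCl3 array alone, at least 1.49-fold higher, while Tapbp lay at -0.95 (-1.63 to -0.27). The 3 brightest members, looked up after the list's values were seen, lay below 0, with B2m, the light chain of MHC class I, at -0.30 (-0.55 to -0.04; 0.11 on its second probe), H2-D1 at -0.15 (-0.42 to 0.11) and Psmb10 at -0.06 (-0.29 to 0.18). With no filter on dim probes the list lay at percentile 96.1. In all, 7 lists stood apart, where lists of genes drawn at random would give 2.45. Genes of a list can move together and some lists share members, so this number does not measure chance between 2 samples.

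**Figure D1:**
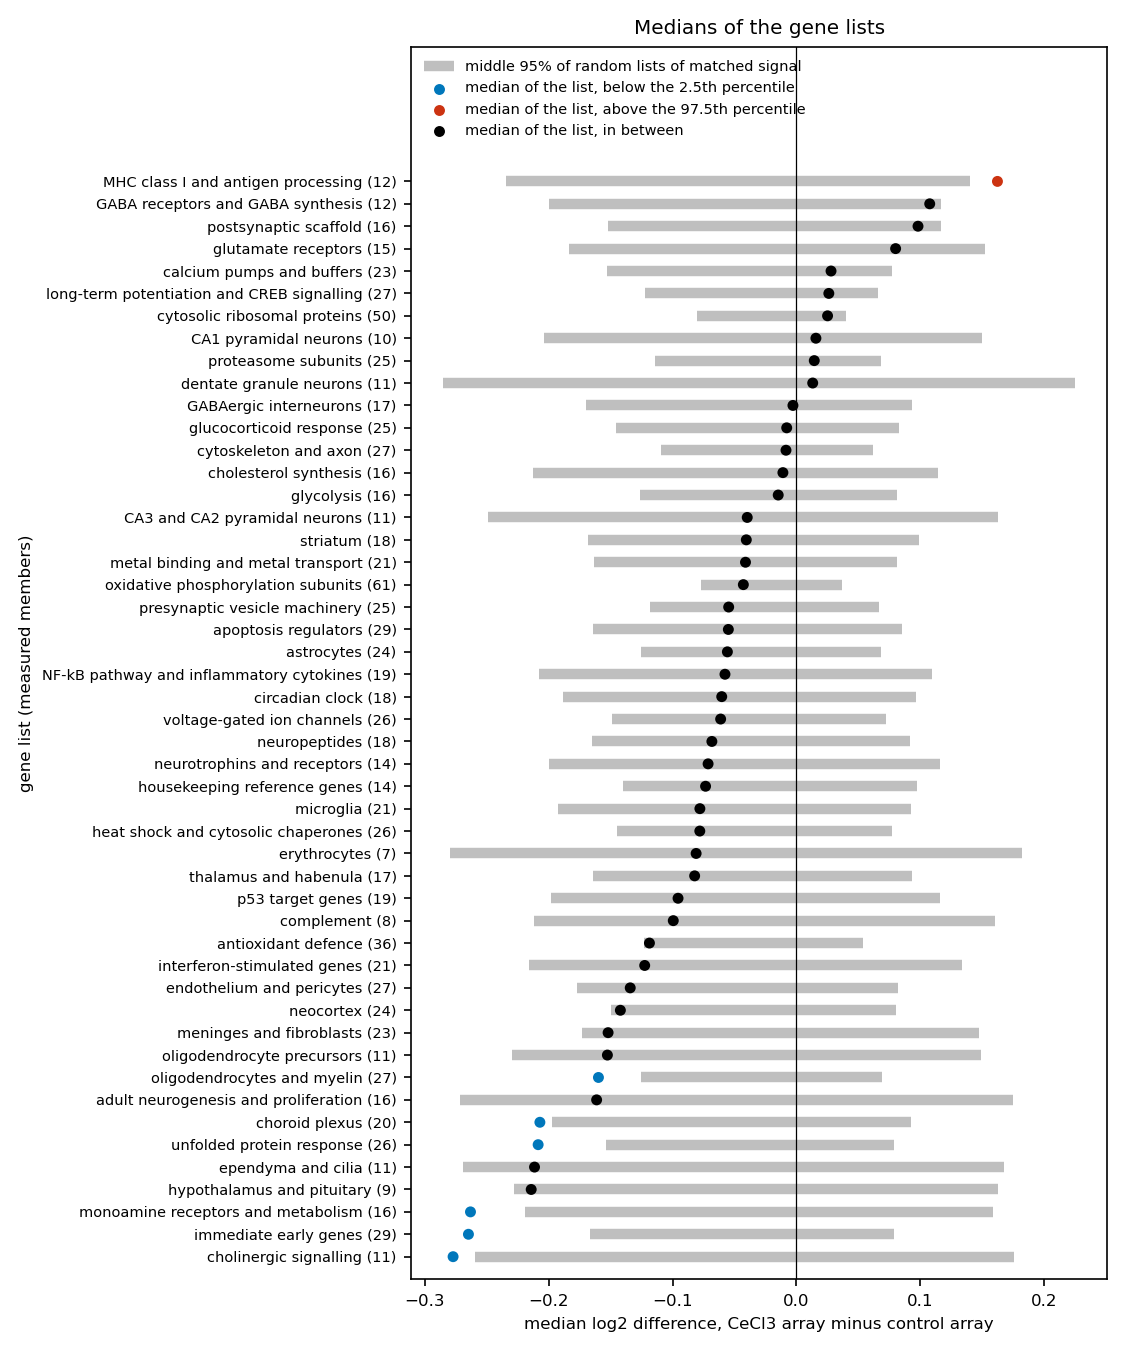
Points show the median log2 difference, CeCl3 array minus control array, of each of 49 gene lists, and grey bars the middle 95% of 10000 random lists matched on signal; the number of measured members stands after each name. Immediate early genes (-0.26) and cholinergic genes (-0.28) lie left of their bars, and MHC class I genes (0.16) to the right of theirs.

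**Figure D2:**
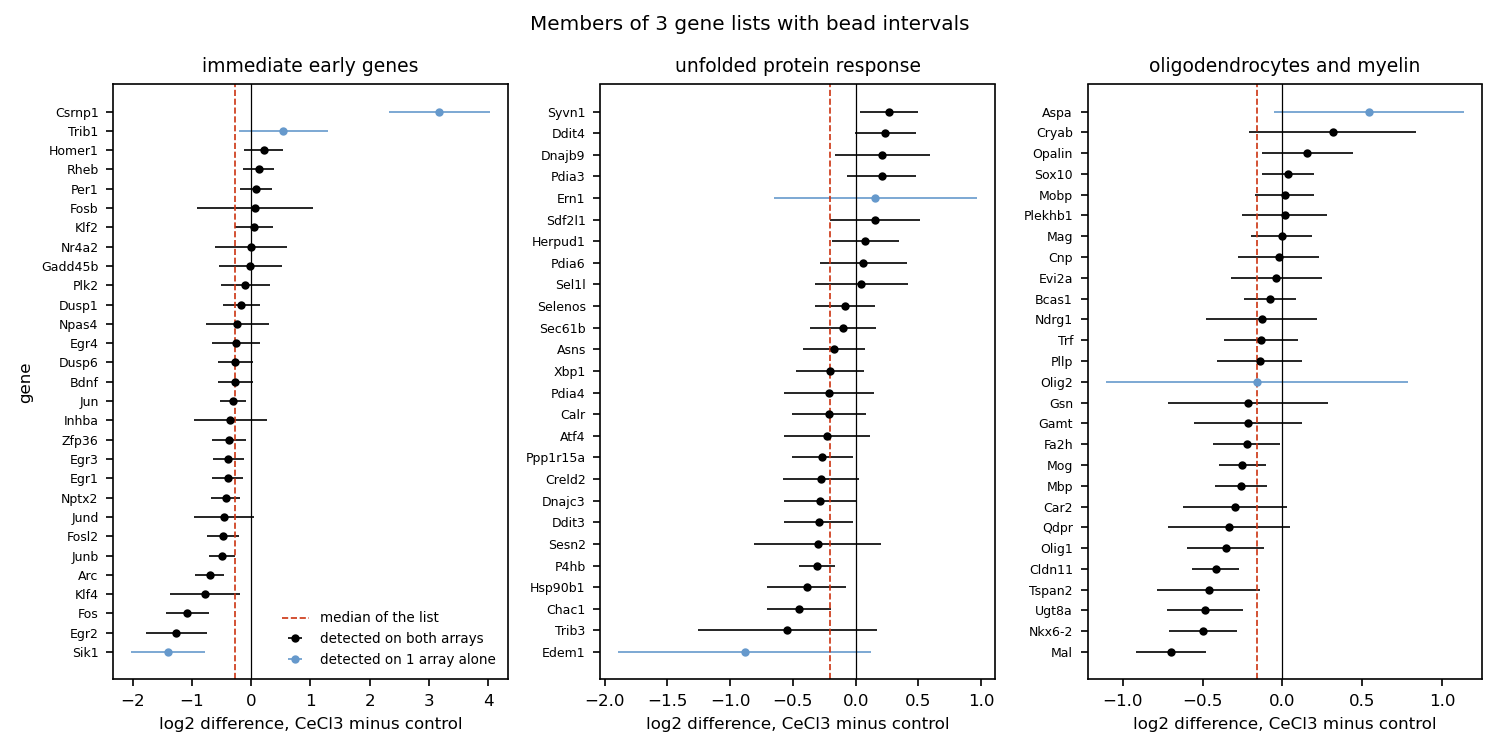
Points show the log2 difference, CeCl3 array minus control array, of each measured member of 3 lists, with 95% bead intervals as bars; blue points are genes detected on 1 array alone, drawn at measured values that include background. Among immediate early genes 22 of 29 lie below 0, and Csrnp1, at least 7.46-fold higher, lies above.

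The lists of GABA receptors, glutamate receptors, postsynaptic scaffold and long-term potentiation did not stand apart, although the first and the third did under 1 of 10 alternatives each. GABA receptors and GABA synthesis (median 0.11, percentile 96.7) lay at percentile 99.97 with the mean of each gene's probes. The postsynaptic scaffold list (median 0.10, percentile 95.9) lay at percentile 99.5 for genes detected on both arrays, and at 25.7 with the mean of probes. Grin2b, a subunit of the NMDA receptor, was at 0.24 (0.02 to 0.45), the AMPA receptor subunit Gria1 at 0.08 (-0.14 to 0.30) on its brightest probe and at 0.83, 0.33 and -0.01 on others, Camk2a at 0.02 (-0.22 to 0.25; 0.29 on its second probe) and Creb1 at -0.35 (-0.66 to -0.05). Grin2a was detected on the CeCl3 array alone, on a probe designed on a cDNA clone, with no bound above 1. The glutamate receptor list had a median of 0.08 (percentile 88.3; 9 of 15 higher) and the list of long-term potentiation and CREB signalling 0.03 (percentile 87.3; 16 of 27 higher). Doublecortin, Dcx, a marker of young neurons, lay at 0.29 (-0.08 to 0.66), with a second probe detected on the CeCl3 array alone at least 1.07-fold higher, and Prox1, a marker of dentate granule cells, at 0.06 (-0.20 to 0.33).

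Antioxidant genes had a median of -0.12 (percentile 3.15, or 1.64 with the mean of probes), with 22 of 36 members lower. Sod1 (0.01, -0.31 to 0.32), Sod2 (-0.18, -0.54 to 0.17), Cat (-0.22) and Gpx1 (-0.01, -0.32 to 0.30) all had intervals that held 0. Of the metallothioneins, Mt2 was lower at -1.17 (-1.78 to -0.55) on its 1 detected probe. That probe was dim, with a log2 signal of 6.39 (CeCl3) and 7.55 (control). Mt1 lay at 0.00 (-0.13 to 0.13) with a log2 signal of 15.79 on both arrays, near the top of the scale. Mt3, with a log2 signal of 13.2 (CeCl3) and 13.3 (control), lay at -0.07 (-0.26 to 0.13). The list of metal binding and transport had a median of -0.04 (percentile 50.4). Apoptosis regulators had a median of -0.05 (percentile 38.6). Within that list Bcl2 lay at -0.46 (-0.79 to -0.13) and -0.38 on 2 probes, and a dim probe was detected on the CeCl3 array alone with no bound above 1. The NF-kB and cytokine list had a median of -0.06 (percentile 46.5). Hmox1, Tnf and Il1b were not detected on either array, and Grin1, Bax and Nfkb1 have no probe named here.

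The lists of astrocyte, microglial and erythrocyte genes did not stand apart, although the microglial list did, on the lower side, under 3 of 10 alternatives (percentile 2.37 with the mean of probes). Astrocyte genes had a median of -0.06 (percentile 31.3; Gfap at 0.14, -0.13 to 0.41), microglial genes -0.08 (percentile 34.9; Aif1 at 0.22 and -0.52 on its second probe) and erythrocyte genes -0.08 (percentile 37.2; Hba-a1 at -0.11, -0.28 to 0.06). The reference genes Actb (-0.01, -0.18 to 0.17) and Gapdh (-0.10, -0.27 to 0.07) lay near 0, though other Actb probes lay at -0.51, 0.12 and 0.19 and a dim one was 2-fold lower.

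Probes of the same gene gave the one internal check that the design allows. The 2 brightest probes were compared in 3652 genes with at least 2 detected probes. They differed between the arrays in the same direction in 55.3% of genes (Wilson 95% interval 53.7 to 56.9). The share was 49.8% in random pairs (middle 95% of the pairings 48.2 to 51.4). Across the 3652 genes, which are not independent replicates, the differences of the 2 probes correlated with r = 0.16. Of 50 genes whose brightest probe was past 2-fold, 30 had a second probe in the same direction and 12 a second probe also past 2-fold. The spread between probes of a gene was 0.28 on the log2 scale. It was taken as the SD, over genes, of the difference between the values of the 2 probes divided by 2.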

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

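Of 490 alternative values of the 49 lists, 470 kept their side of the threshold, 10 lost it and 10 gained it. The 7 lists that stood apart kept their direction relative to all genes in all 70 values. The other 42 changed it in 63 of 420 values, with the widest moves under the mean of probes, in hypothalamus and pituitary (-0.18 to 0.07) and postsynaptic scaffold (0.14 to -0.04). Of 918 values for named genes, 802 moved by less than the spread between probes and 116 by more; 19 changed sign, 16 of them from a difference smaller than that spread, such as Aif1 (0.22 to -0.15) with the mean of probes. Immediate early, monoamine, unfolded protein response and myelin genes stood apart under all 10 alternatives. The series matrix moved the median of all genes from -0.04 to 0.18 (centred, -0.10), so list values are read relative to it. Centring, RefSeq probes and, for counts, cyclic loess were chosen after seeing the data. The cause was not tested unless stated.

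Counts depended most on dim signal. Against 509 higher and 247 lower, offset 50 gave 143 and 43, by shrinking dim differences, and detection on both arrays 103 and 53, by leaving fewer features; a threshold of 1.5-fold gave 1145 and 762. The series matrix gave 1144 higher, RefSeq probes, which leave out unnamed probes, 246 higher (289 among named genes), no background correction 380 lower and no filter 409 lower. The higher share of 2-fold differences, 67.3%, was 85.4% in the series matrix, 57.8% with no filter and 55.0% on RefSeq probes; among named genes it was 58.7%, and 49.5% for those detected on both arrays. The same-sign share was 52.5% with no filter, 67.5% in the series matrix (random pairs 63.5%) and 57.1% when centred (52.0%); it has no value for the mean of probes.

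The cholinergic median was -0.19 for genes detected on both arrays. MHC class I no longer stood apart with no filter (0.093), in the series matrix (0.43) or centred (0.14). Choroid plexus no longer did with cyclic loess (-0.16), offset 50 (-0.17), both arrays (-0.21), the mean of probes (-0.11), the series matrix (0.079) or centred (-0.21). Lists that came to stand apart were GABA receptors, cytoskeleton, antioxidant and microglia with the mean of probes, microglia in the series matrix and centred, postsynaptic scaffold for both arrays, neocortex with offset 50 and no filter, and hypothalamus and pituitary with no filter. Other probes were read for Sntb2 (-0.50) and Vwa5b2 (-0.63, on a probe detected on the control array alone) with RefSeq probes, and for Bcl2 (0.18, with a probe detected on the CeCl3 array alone) with the mean of probes. No paired analysis was possible because each group has 1 array; leaving one out was not possible either.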

Other observations

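Among the members of lists that did not stand apart, some genes differed beyond their bead intervals; they were chosen after their values were seen. The AMPA receptor subunits Gria2 (0.69, bead interval 0.40 to 0.97) and Gria3 (0.79, 0.41 to 1.16) were higher on their brightest probes on the CeCl3 array. Other probes lay at 0.19 and -0.25 for Gria2 and -0.17 for Gria3. A further Gria3 probe, detected on the control array alone, was at least 1.31-fold lower, with a bead interval (-1.45 to 0.44) that held 0. The GABA receptor subunit Gabrg3 lay at 0.85 (0.36 to 1.35) on its 1 detected probe, which was designed on a cDNA clone, a class of probe that lay higher on the CeCl3 array. Of the interferon-stimulated genes 16 of 21 were lower (median -0.12, percentile 18.3), among them Gbp2 (-0.48, -0.78 to -0.18) and Ifi35, detected on the control array alone and lower by at least 0.59 log2. Among microglial genes Ly86 (-0.39, -0.74 to -0.04) and C1qc (-0.30, -0.55 to -0.06) lay lower beside Fcrls. The antioxidant genes Prdx2 (-0.49, -0.73 to -0.25; 0.04 on a dimmer probe), Gclm (-0.54, -0.88 to -0.20) and Txn2 (-0.52, -0.86 to -0.18) lay lower. The apoptosis receptor Fas lay at -0.75 (-1.17 to -0.33).

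Single probes gave some of the widest gaps, also chosen after their values were seen. One probe of Mrpl10 lay at -4.10 (-4.44 to -3.76) while the brighter lay at 0.09, and one probe of Gnaq, detected on the CeCl3 array alone, was at least 9.79-fold higher while the brighter lay at 0.35. Both detected probes of Rbm8a were lower, at -2.60 and -1.37. A probe with no gene named here, ILMN_2899599, was at least 43.2-fold higher on the CeCl3 array, and another, ILMN_2529458, at least 34.9-fold.

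In the 3 patterns that follow, the tests of stray probe signal for Xist and of blood for the neutrophil genes were chosen after the values they measure had been seen, and a value counted for or against an explanation if it passed its bound by more than its spread, a rule also set after the first values were seen. Without that rule the bounds set beforehand alone would have counted for female RNA in the control sample and against neutrophils in the CeCl3 sample, which are left open here. All 4 Xist probes were detected on the control array and 0 on the CeCl3 array, which argues against stray signal of single probes. The Xist probes had log2 signals of 7.3 to 9.7 on the control array and of 4.5 to 4.8 on the CeCl3 array. RNA of female mice in the control sample, or a wrong label of sex, would give such values. This explanation stays open because the further test rests on 4 genes, too few to decide it. The 4 held-out genes that escape X inactivation, Ddx3x, Pbdc1, Car5b and Mid1, were all lower on the CeCl3 array, with a median of -0.20 relative to all genes, past the bound of -0.1 set beforehand. Yet random lists of matched signal reach such a median often (percentile 25.9), and each bead interval held 0; of the 2 measured escape genes seen before the test, Eif2s3x lay at -0.16 (-0.41 to 0.09) and Kdm6a at -0.23 (-0.42 to -0.03), so that all 6 were lower on their brightest probes and 1 of these intervals lay below 0. Of 12 probes for Y-linked genes 1 was detected on the CeCl3 array and 0 on the control array, too dim to tell the sex of either sample.

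Within 567 genes, probes designed on cDNA clones lay higher on the CeCl3 array than RefSeq probes of the same gene, by a median of 0.35 log2, in 73.7% of genes. The other ways of normalizing or correcting background run here did not remove it, since the lowest median under them was 0.27. All of them start from deposited values that were already background-subtracted, so a cause in that earlier step cannot be excluded. Dim signal of the clone probes may account for part of it, as 119 pairs matched on signal gave a median of 0.14. The standard error of their mean was 0.056, which leaves that median too close to the bound of 0.1 to decide. More unspliced or nuclear RNA on the CeCl3 array could give this too, and the 5 such RNAs seen first, Meg3, Miat (1.03), Neat1 (0.66), Rian (0.72, on a clone probe) and Snhg11 (1.01), were higher. But 9 held-out non-coding RNAs, from a list written for nuclear-retained RNAs, had a median of 0.24 (0.04 with 2 genes detected on 1 array alone at their bound). They lay at percentile 94.9, within the random range. Members such as Norad (0.04) and Oip5os1 are not mainly nuclear, so the list is a weak test and this stays open. Of the 7 held-out RNAs detected on both arrays 4 were higher, 2 with bead intervals above 0. The other 3 were lower, among them Pantr1 (-0.52, -0.85 to -0.20). Before H19 was found to have been read as Nckap1 the percentile was 89.6.

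Of 9 neutrophil genes first noticed, 8 were measured: S100a8 and Lcn2 were higher on the CeCl3 array, and S100a9 (at least 1.32 log2), Ltf (1.94), Retnlg (0.92), Ngp (0.62), Camp (0.46) and Mpo (no bound above 1) were detected on it alone, so that the median at their bounds was 1.12 log2. More blood in the CeCl3 sample as the whole cause would call for higher erythrocyte genes too. The 4 that are not globins, whose 3 probes lie near the top of the scale, had a median of -0.0099 (SD 0.53), under the 1.12 above. Alas2 lay at 0.54 (0.14 to 0.93), Slc4a1 at 0.11 (-0.29 to 0.51), Ube2l6 at -0.13 (-0.56 to 0.30) and Fech at -0.73 (-1.32 to -0.14). They went both ways, and their median was below 0 by less than this SD. Genes that other cells express too would also rise less, so blood stays open. Neutrophils, or their RNA from another source, may be present, yet 13 held-out neutrophil genes gave a median of -0.07 at percentile 37.0, and of the 9 detected on both arrays 8 were lower, Prtn3 (-0.90, -1.52 to -0.28) and Pglyrp1 (-0.50, -0.80 to -0.20) with bead intervals below 0, while Mmp9 was higher (0.40) with an interval that held 0. Genes detected on both arrays had signal on the control array too, so other cells may account for them. That tally therefore cannot decide, and the median was below 0 by less than the spread of random lists. The other 4 of the 13 were detected on the CeCl3 array alone (1, Pla2g7, with a bound above 1, though its bead interval held 0). The held-out list named 39 genes, and Cxcr2, Mmp8, Cd177 and Ctsg were among those detected on neither array. Some of the 13, such as Lyz2 (-0.01) and Coro1a (-0.10), are also expressed by microglia, so the presence of neutrophils stays open. No explanation through CeCl3 itself was tested, since treatment, BeadChip and sample cannot be told apart with 1 array per group. If the control RNA came from female mice, sex cannot be told apart from these either.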
